A study of Drosophila melanogaster with 4 samples.

How the data were processed

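ChIP-seq with the antibody Q2642 against dSFMBT was done on larvae of the wild-type strain Oregon-R at the third instar. The 4 samples comprised 2 ChIP replicates and 2 inputs, grouped and numbered by their titles. Larval tissue was homogenised and fixed with formaldehyde and the chromatin was sonicated, per the labels' protocols. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The coordinates are FlyBase release 5, per the file headers. The caller of the enriched regions, its threshold, the use made of the inputs, the treatment of reads with several matches and the way replicates were combined are not given in the sources used here.

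The deposited files were 3 lists of enriched regions, 1 for each ChIP replicate and 1 for the replicates combined. The authors gave each region a start, an end and 1 score, and these deposited scores were treated as log2 values. The headers do not state the scale. It was read from the values, by comparing the 12 most frequent scores of each list in all 66 pairs. Differences matched log2 of a ratio with a denominator of at most 40, within a tolerance of 1e-07, in 16 pairs of the combined list, 44 pairs of replicate 1 and 24 pairs of replicate 2. Natural log and base 10 gave 0 matches in each list. What the ratio is relative to is not stated, so a score was used only to describe, rank or filter regions within its list and to compare overlapping regions between lists. The smallest region was 1301 bp in each replicate list and 1001 bp in the combined list, so the lists were not made with the same lower limit of width. The files gave no read counts, so depth per library is unknown and no interval that needs it was computed. Intervals on shares of regions cover counting error only.

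Lists were compared with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15. A region was shared when it overlapped by at least 1 bp. The main set was made of combined-list regions that overlapped a region of each replicate list, and a region's replicate score was the highest among those it overlapped. That score can belong to 1 of several pieces or to a region shared with a neighbour. Some differences between replicates can therefore come from the matching. Chance values came from 1000 random placements of the regions, without overlap and with widths kept, within their own sequence. Placement used the whole assembled length, including any part that reads cannot map to, which can lower the chance values. Counts per arm were tested with two-sided exact binomial tests against arm lengths from the file headers, adjusted over the 6 arms by the Benjamini-Hochberg method. Grouping was the share of regions with another within 10 kb. The threshold was 0.05 throughout. The overlap counts were checked against bedtools 2.31.1 on simulated lists, where both gave 1244 of the replicate 1 regions. On simulated unrelated lists of the sizes of replicates 1 and 2, 6 of 100 had an overlap p under 0.05, and 1 of 100 simulated placements had a grouping p under 0.05. These simulations used the same random placement as the chance values, so they check the computation and not whether that placement suits real lists. With a 1.3-fold density planted on 2R, 100 of 100 simulations called that arm, and with none planted 3 of 100 made a call. The arm simulations drew regions independently, so they do not check the binomial test on regions that lie in groups, as the shared regions did.

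The tests, their alternatives and the rule for named regions were set before the data were examined. The rule named the 10 shared regions with the highest combined score and the 5 widest. Its other parts named genes, and could not be applied. The share of regions at promoters, the enrichment of fixed gene lists and the enrichment of fixed motifs were planned and were not analysed here, because they need an annotation or genome of release 5 and the gene table at hand was of release 6. Alternatives were the replicate lists alone, the whole combined list, regions at or above the median score, a stricter overlap of 50% of the region's length, a neighbour distance of 50 kb, and width or covered length in place of score or number. Regions with a ratio above 2, the 100-kb windows, the 300-kb stretch, and the comparison of replicate scores by size of difference were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.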

Results

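Chromatin immunoprecipitation followed by sequencing was used to map dSFMBT in wild-type Oregon-R larvae of Drosophila melanogaster at the third instar. dSFMBT is a Polycomb group protein that carries MBT domains and pairs with the DNA-binding protein Pho in the complex PhoRC. The samples fell into a ChIP group of 2 replicates, precipitated with the antibody Q2642, and an input group of 2 replicates. Each ChIP replicate had a list of enriched regions, and a further list combined the replicates. The inputs had no list of their own, so no region was measured in them separately here. Replicate 1 held 5514 regions and covered 12.8 Mb, replicate 2 held 6004 regions and covered 15.1 Mb, and the combined list held 9756 regions and covered 23.8 Mb. Read depth per library was unknown from these files. Each region carried 1 score from the authors, which lay on a log2 scale, and ratios given below are 2 raised to that score. Positions are in FlyBase release 5, and no gene was assigned to a region, because the gene table at hand belonged to another release.

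The comparison of the ChIP replicates asked which regions were found again in a second library. Of the 5514 replicate 1 regions, 4380 overlapped a replicate 2 region by at least 1 bp, which was 79.4% (95% exact Clopper-Pearson interval 78.3 to 80.5%). Random placement of the replicate 2 regions within their chromosomes gave 22.1% ± 0.527 (SD over 1000 placements), so the observed share was 3.60 times the chance share. The one-sided permutation p was 0.001, the smallest that 1000 placements can give. In the other direction, 71.1% of the 6004 replicate 2 regions overlapped a replicate 1 region, against 20.2% by chance (permutation p = 0.001, again the smallest possible). The intervals cover counting error only, and the test compares these 2 libraries, because the labels do not say whether the replicates came from separate collections of larvae.

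Regions with high scores were found in both libraries most often. In the highest quartile of the replicate 2 list, with scores from 0.78 to 3.87, 94.0% of 1501 regions were found in replicate 1 (95% exact interval 92.7 to 95.2%). In the lowest quartile, with scores from 0.14 to 0.45, 45.0% of 1501 were found (42.5 to 47.6%). The replicate 1 list changed less across its range. Its highest quartile was found in replicate 2 at 90.9% (89.3 to 92.4%) and its lowest quartile at 77.9% (75.6 to 80.0%), while the next quartile up had the smallest share, at 72.5% (70.1 to 74.8%).

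**Figure D1:**
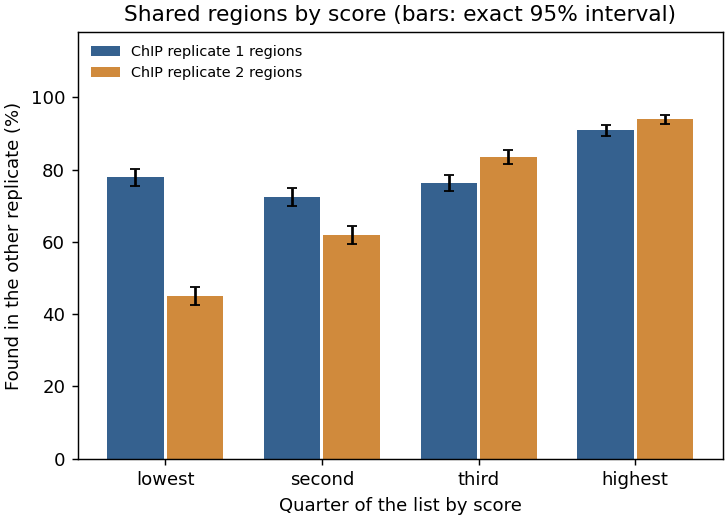
Percent of regions of each ChIP replicate that overlapped a region of the other replicate, by quartile of its own list from the lowest to the highest score; error bars are exact 95% intervals. The share for replicate 2 climbed from 45.0% in the lowest quartile to 94.0% in the highest, and replicate 1 lay between 72.5% and 90.9%.

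In the combined list, 4036 of the 9756 regions (41.4%) overlapped a region of each replicate. These 4036 regions, called shared below, are the main set, and other lists are named where they are used. A further 965 combined-list regions overlapped replicate 1 alone, 1626 overlapped replicate 2 alone, and 3129 (32.1%) overlapped neither list. The 4036 shared regions had a median width of 2878.5 bp and a median score of 0.56, a ratio of 1.48. The regions found in neither replicate list were narrower and scored lower, with a median width of 1251 bp and a median score of 0.37. The 10 highest scores of the whole combined list, up to 3.84, all belonged to regions at most 1.72 kb wide, and 0 of those 10 were in the shared set. Of the 606 combined-list regions with a ratio above 2, 471 were found in both replicates and 117 in neither. Of those 117, 64.1% lay outside the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X, and their median width was 1035 bp.

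The positions of the shared regions were close between libraries. Among the 3535 shared regions with 1 region in each replicate, the centres in the replicates lay a median of 139 bp apart, and 90% lay within 647 bp. Shared regions were chosen by overlap, which limits this distance in part, and no chance distance was computed. Scores followed each other across the 4036 regions with a Spearman rho of 0.70 (bootstrap 95% interval 0.68 to 0.71) and a Pearson r of 0.81. This correlation is across regions, which are not independent replicates. Of the 100 regions with the highest score in replicate 1, 65 were also among the 100 highest in replicate 2, where independent rankings would share 2.48. The median difference, replicate 2 minus replicate 1, was 0.03, with means of 0.75 in replicate 2 and 0.69 in replicate 1. The median SD between the replicates of a region was 0.077. Combined-list scores followed replicate 2 (rho = 0.94) more closely than replicate 1 (rho = 0.81).

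**Figure D2:**
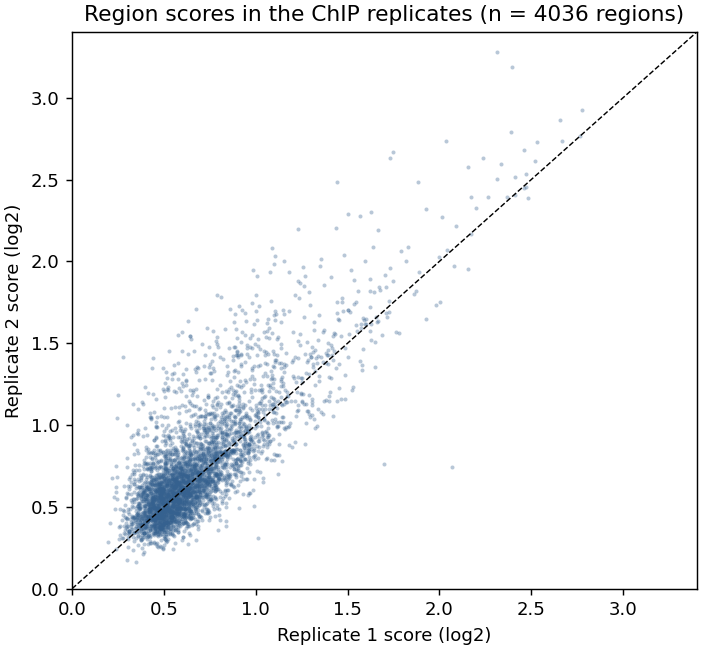
Score of each of the 4036 shared regions in ChIP replicate 1 (x axis, log2) and ChIP replicate 2 (y axis, log2); the dashed line marks equal scores. Points follow the line with a Spearman rho of 0.70, and a group of points lies above it.

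The 10 shared regions with the highest combined score had ratios from 5.45 to 7.36 and widths from 2429 to 4320 bp. 4 of them lay on 3R, 2 on X and 9 on the arms. Scores given with an SD here and below are means of the 2 replicate scores, while the ranking used the combined score. The region of 3R from 27896184 to 27899626 ended 5427 bp before the end of the assembled arm and had a score of 2.85 ± 0.11 (SD, n = 2). The region of 3R from 12588526 to 12591189 had a score of 2.77 in each replicate. A second region of the same part of 3R, from 12773302 to 12775732, scored 2.76 ± 0.14 (SD, n = 2). The X chromosome held a region from 17661104 to 17663739 at 2.57 ± 0.066 and a region from 5417336 to 5419911 at 2.79 ± 0.56 (SD, n = 2). The remaining arm regions lay on 3L from 6895900 to 6898501 at 2.59 ± 0.28, on 2R from 20072687 to 20077006 at 2.57 ± 0.16, on 2L from 3537430 to 3541581 at 2.50 ± 0.047 and on 3R from 4015576 to 4018004 at 2.46 ± 0.076 (SD, n = 2 for each). The highest combined score, 2.88, belonged to 3RHet from 2348216 to 2351745, a heterochromatic sequence assembled apart from the arms. Of the 10, it had the widest gap between replicates, with 2.31 in replicate 1 and 3.28 in replicate 2. How reads with several matches in the genome were treated is not given in the sources used here, so the values on such sequences are uncertain. Combined-list scores followed replicate 2 more closely, so a ranking by combined score favours regions that were high in replicate 2.

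The widest shared regions were a different group from the 10 with the highest scores. The 5 widest had combined scores from 0.69 to 0.86. These were below the scores of the 10, which were picked by score, and above the median of all shared regions, 0.56. They spanned 3LHet from 590951 to 611596 (20646 bp), 2R from 8897904 to 8918457 (20554 bp), 3R from 12065415 to 12083916 (18502 bp), X from 6637036 to 6654986 (17951 bp) and 2L from 22166362 to 22184003 (17642 bp). The replicate lists split all 5 but 3LHet into at least 2 pieces in each library, and the 3LHet region was 1 piece in replicate 2 and 3 pieces in replicate 1. In total 68 of the 4036 shared regions were wider than 10 kb.

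The next comparison set the number of shared regions on each arm against its length. Chromosome 4, the small dot chromosome, and arm 2R held more regions per Mb than the mean of 32.3 over the 6 arms, and 2L and 3L held fewer. Arm 2R had 820 regions, 38.8 per Mb (95% exact interval 36.4 to 41.2), which was 1.20 times the expected number (two-sided exact binomial test, Benjamini-Hochberg adjusted over the 6 arms, p = 1.2e-07). Chromosome 4 had 61 regions, 45.1 per Mb (34.6 to 57.8), 1.40 times the expected number (adjusted exact p = 0.018). The excess on chromosome 4 was 1.25 times and did not pass the test among the regions at or above the median score (adjusted exact p = 0.28). In the whole combined list chromosome 4 had 190 regions, 1.87 times the expected number, so the size of its excess depends on the requirement of both replicates. Arms 2L and 3L had 29.2 and 29.1 regions per Mb, 0.90 times the expected number for each (adjusted exact p = 0.0066 and 0.0038). On 3R (32.8 per Mb) and X (31.6 per Mb) the numbers did not differ from expectation by the test (adjusted exact p = 0.59 for both). Among the regions at or above the median score, however, X held 1.17 times the expected number (adjusted exact p = 0.00052). That limit was 1 median over all sequences, and X had a higher median score, 0.61, than 2L, 2R, 3L and 3R together, 0.55. With a ratio above 2, X had no larger share of its regions, 10.7% (95% exact interval 8.54 to 13.2%) against 12% on those arms (10.9 to 13.2%). The test treats regions as independent draws, whereas the shared regions lay in groups, so its p-values can be too small.

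**Figure D3:**
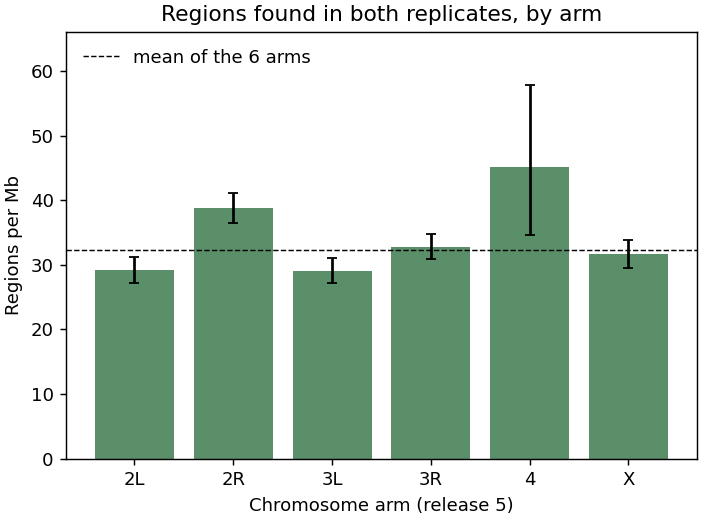
Shared regions per Mb on each chromosome arm; error bars are exact 95% intervals for counting error and the dashed line is the mean of the 6 arms, 32.3 per Mb. Arm 2R, at 38.8 per Mb, and chromosome 4, at 45.1 per Mb, lie above the line, and 2L and 3L lie below it.

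Heterochromatic sequences assembled apart from the arms held 114 shared regions in 9.28 Mb, 12.3 per Mb, and the unplaced sequence U held 31 in 10.0 Mb. 3LHet held 41 of them, 2RHet 39 and 3RHet 27, while YHet held 0. The requirement of both replicates removed a larger part of the combined list on the heterochromatic sequences than on the arms. It left 114 of 524 regions on the former and 3891 of 9071 on the latter. The density of shared regions thus depends on that filter, and the treatment of reads with several matches is not given.

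Shared regions lay closer together than random placement would put them. Of the 4036 regions, 68.3% had another shared region within 10 kb, against 50.9% ± 0.88 (SD over 1000 placements) by chance (one-sided permutation p = 0.001, the smallest possible). The share had no lower limit on the gap, so neighbours only a few bp apart were counted. Some of these neighbours had the same score in a replicate, as when both overlap a single replicate region. Pieces of a single region split by the caller can therefore add to the share, and how far they do was not tested. At 50 kb, where chance gave 96.0%, the observed share was 95.6% (permutation p = 0.94). Windows of 100 kb were examined after the data had been seen. Those with the most regions were 3R from 12.7 to 12.8 Mb and 2R from 8.8 to 8.9 Mb, with 12 each. They differed in score, since 6 of the 12 regions on 3R had a ratio above 2, against 2 of the 12 on 2R. The 2R window was covered over 60.3 kb and the 3R window over 31.1 kb.

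The stretch of 3R from 12.5 to 12.8 Mb, chosen after its values were seen, held more regions with a ratio above 2 than any other 3 adjacent windows. It held 29 shared regions, 14 of them with a ratio above 2, and 24.5% of its length lay inside shared regions. Beside the 2 regions among the 10 highest by combined score, it contained regions from 12693758 to 12697423 at 2.70 ± 0.051, from 12636387 to 12638804 at 2.41 ± 0.13, from 12794024 to 12797168 at 2.36 ± 0.30 and from 12723652 to 12726854 at 2.28 ± 0.16 (mean of the replicate scores and SD, n = 2 for each). The region from 12693758 had a combined score of 2.444, just below the lowest of the 10, 2.446. Taken alone, the replicate 1 list had 13 regions with a ratio above 2 in this stretch and the replicate 2 list had 14. Outside this stretch, the 100-kb window with the most regions above a ratio of 2 was X from 5.4 to 5.5 Mb, with 5 of 7 regions. The windows X from 17.6 to 17.7 Mb (4 of 9 regions), X from 8.5 to 8.6 Mb (4 of 8) and 3L from 9.0 to 9.1 Mb (4 of 5) followed with the same number.

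**Figure D4:**
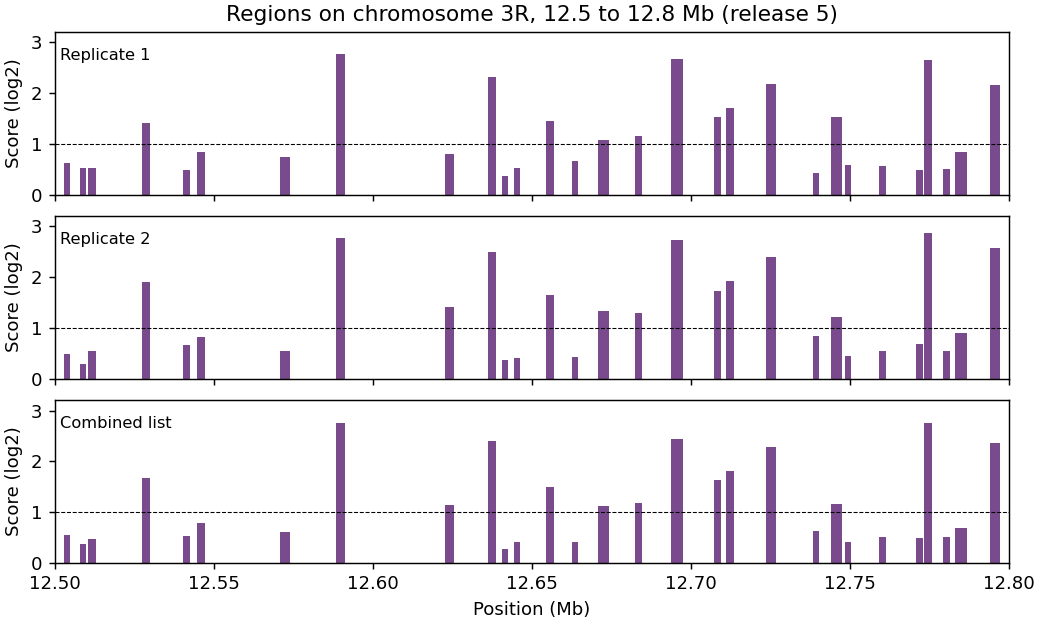
Map of the 29 shared regions on 3R between 12.5 and 12.8 Mb (x axis, release 5), drawn to scale in width, with the score in each ChIP replicate and in the combined list (y axis, log2); the dashed line marks a ratio of 2. In the combined list 14 regions stand above that line, separated by regions with lower scores and by sequence outside any shared region.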

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

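Leaving out a replicate for the number of shared regions, for the named regions and for the similarity of adjacent scores, the scores at or above the median for the rank correlation, and the 6 arms alone for the number of shared regions and the rank correlation, were chosen after seeing the data. The replicate overlap stayed between 71.5% and 80.2%, with a permutation p of 0.001, when 50% of the region had to be covered, when only regions at or above the median score of each list were used, and on the 6 arms alone. The number of regions found in both replicates was 3662 when 50% of the combined-list region had to be covered by each replicate and 1881 for replicate regions at or above the median score, where fewer regions entered by construction. With 1 replicate list required in place of both, it was 5001 to 5662. The rank correlation of scores was 0.64 for widths in place of scores and 0.55 within the regions at or above the median score, whose range is narrower by construction. Arms 2R, 2L and 3L kept their direction and their call in every region set tested, and their direction by covered length. Chromosome 4 had 1.25 times the expected number and no call among regions at or above the median score, where fewer regions entered, and kept the call with each replicate left out. The values for 3R, never past the threshold, fell below 1 in the whole combined list (0.97), at or above the median score (0.99), by covered length (0.95) and with a replicate left out (0.97 to 0.98). Those for X rose above 1 with a replicate left out (1.01 to 1.03), by covered length (1.04) and at or above the median score (1.17), the last past the threshold with 1 median as the limit on all arms and a higher median score on X. The cause was not tested otherwise. Grouping within 10 kb kept its call in every region set tested, and at 50 kb it gave 95.6%, below the chance share of 96.0%, where nearly every region has a neighbour by chance. None of these sets merged regions a few bp apart, so splitting by the caller stays open for the grouping. Of 30 scores of the 15 named regions in a single replicate, 20 lay within 1 replicate SD of the combined score and 10 lay further away. With 2 replicates that SD is set by their own difference, so the count does not measure stability. The 3RHet region among the 10 highest, at 2.31 and 3.28, counted as within. The 3R region from 12588526 to 12591189, at 2.77 in each replicate, counted as further away. No paired analysis was possible because the inputs had no list of regions and no result came from a test between groups. The planned promoter, gene list and motif results were not run. Read depth, unknown here, limits what can be said of a region absent from a list.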

Other observations

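All tests in this part were chosen after the data were seen, and so were their bounds: the ratio of 2, the 100-kb windows, the 300-kb stretch, and the limits on score differences. Ends of the assembled arms often carried a shared region: 7 of the 12 ends of the 6 arms had one within 10 kb. The 3R region ending 5.43 kb before the right end ranked 3 of 4036 by combined score, and a 2L region beginning 5.08 kb from the left end scored 2.16 and ranked 25, with 2.47 in replicate 1 and 2.45 in replicate 2. The right end of chromosome 4 had a region at 1.21, the left end of 3R one at 1.17 and the right end of 2R one at 1.07. The left end of chromosome 4 and the right end of X had regions with lower scores, 0.69 at each, ranked 1283 and 1267. The left end of 3L had its first shared region 65.8 kb in, at 0.61. No comparison with chance was made for the ends.

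Shared regions on X had a higher median score, 0.61, than those on 2L, 2R, 3L and 3R together, 0.55, a difference of 0.06 (bootstrap 95% interval over regions 0.04 to 0.09). At the 90th percentile the difference was -0.04 (-0.12 to 0.06) by combined score. There it was 0.05 (-0.02 to 0.12) by replicate 1 scores and -0.09 (-0.17 to 0.05) by replicate 2 scores. In the whole lists it was 0.04 (0.0003 to 0.10) in replicate 1, -0.07 (-0.11 to 0.01) in replicate 2 and 0.02 (-0.04 to 0.05) in the combined list. Of the shared X regions, 10.7% had a ratio above 2 (8.54 to 13.2%), against 12% on the autosome arms (10.9 to 13.2%). A lower read number on X, which would raise the lowest score that is called, was tested in 2 forms, and the replicates did not settle it. The separate intervals did not decide. The difference at the 90th percentile minus that at the 10th, which this explanation puts below 0, was -0.10 (-0.17 to 0.01) by combined score, -0.01 (-0.08 to 0.05) by replicate 1 scores and -0.15 (-0.23 to -0.01) by replicate 2 scores. In the whole lists it was -0.03 (-0.07 to 0.03) in replicate 1, -0.13 (-0.18 to -0.06) in replicate 2 and -0.04 (-0.09 to 0.0011) in the combined list. Replicate 2 thus went as the explanation predicts. The intervals by replicate 1 scores and by combined scores held 0, and the explanation stays open.

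Of 554 shared regions with a mean replicate score above 1, a subset of 156 (28.2%), noticed in the plot of replicate scores, was higher in replicate 2 by more than 0.4 and 2 were higher in replicate 1 by as much. These counts restate how the subset was noticed, but the median difference over all 554, 0.18 (bootstrap 95% interval over regions 0.14 to 0.20), argues against even counting noise around equal scores as the whole cause, while uneven noise stays open, since the depth of the libraries is unknown. A single scale factor would shift every log2 score alike, but the median difference was 0.02 in the 3482 regions with a mean of at most 1, lower than in the 554 by 0.16 (bootstrap 95% interval 0.12 to 0.18), while a difference that grows with the score stays open. Sequences outside the 6 arms cannot be the whole cause, since they held 1.92% of the subset (exact 95% interval 0.40 to 5.5%), and repeats within the arms were not tested. The subset was narrower than the 259 regions whose scores differed by less than 0.2, with median widths of 2694 and 3443 bp (difference -749 bp, -1041 to -549); a difference in recovery between the libraries stays open, and no biological explanation was tested.

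The stretch of 3R from 12.5 to 12.8 Mb held 14 regions with a ratio above 2. Whether high scores group together was asked in 3 ways in turn, each by permuting scores over the same positions within each arm: 44.1% of regions with a ratio above 2 had another within 50 kb against 40.3% (permutation p = 0.087), then the fullest 100-kb window held 6 against a mean of 4.01 (permutation p = 0.012), then the fullest 3 adjacent windows held 14 against a mean of 6.80 and at most 11 (permutation p = 0.001, the smallest possible). The last p covers the search over positions but not the choice of statistic and length, made after the windows were seen, and is too small by an unknown amount; with that limit it argues against region density alone, while the genome-wide share stayed within what permuted scores gave. The median gap between the 14 regions was 13.7 kb (bootstrap 95% interval 9.90 to 18.3), which argues against pieces of 1 split region. The 95th percentile of the permuted counts was 8. For 8 regions above a ratio of 2 to remain, a raised copy number would have to add 0.63 to every score of the stretch. Of combined-list regions, 80.0% scored below that amount, yet 33.3% of the stretch lay inside any combined-list region. That low coverage argues against a gain as the whole cause only if scores and calls used 1 background that the gain leaves unchanged. The background and the use made of the inputs are not given, so the coverage alone did not settle copy number. Of the 29 shared regions in the stretch, 12 scored below 0.63, so with such a gain taken away their scores would be negative. The lowest score of the combined list was 0.069. These scores argue against a gain of that size in every score as the whole cause, while a smaller gain stays open. A cluster of separate strong sites is a hypothesis that stays open, and no biological explanation was tested. Genome-wide, adjacent regions within 10 kb had scores with a rho of 0.081, where permuted scores reached at most 0.071. The rho was 0.066 in the replicate 2 list alone and 0.122 in the replicate 1 list alone, where permuted scores reached at most 0.064 and 0.097 (permutation p = 0.001 for each, the smallest possible). Pieces of 1 region split by the caller were not removed and can add to this small rho, so it does not bear on that hypothesis.

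Combined-list regions found in neither replicate list numbered 3129. The lower minimum width of the combined list cannot account for all of them, since 55% were narrower than 1301 bp and 1408 were wide enough for the replicate lists, and for the 1721 narrower ones it stays open. Sequences outside the arms held 12.1% of them (exact 95% interval 11.0 to 13.3%), against 3.59% of the shared set, too few to be the whole cause. The 1408 wider regions had a median score of 0.34 against 0.56 in the shared set (difference -0.22, bootstrap 95% interval -0.23 to -0.21). Regions found in 1 replicate alone, of any width, scored about as low, with medians of 0.37 for replicate 1 and 0.34 for replicate 2. All 3129 regions in neither list, also of any width, had a median of 0.37. The median score thus did not separate regions in neither list from those in a single list. Weaker regions that passed only on combined reads stay open, and a lower score is also what absence from the replicate lists would select. No biological explanation was tested.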
